A study of Mus musculus with 18 samples.

How the data were processed

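RNA was sequenced from 18 libraries of 15 mouse oocytes each, from WT and Lsm14b KO mice at GV, at MI and 14 h after hCG (denoted as MII), with 3 replicates per group. Per the labels, cDNA was primed with oligo(dT), amplified by Smart-seq2, sheared and made into Illumina libraries. Levels measured this way may depend on poly(A) tails as well as on the amount of mRNA. The deposited table gives each gene as FPKM (fragments or reads per kilobase of exon and per unit of sequencing depth), computed by the authors, in 18 columns and 27874 genes. The labels name mm10 and DESeq2 1.38.3 without a role; the aligner, the counter and the annotation are not given in the sources used here, nor is the strand of the libraries.

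Gene identifiers were matched to GENCODE vM21, in which 27829 were found and 45 were not, and 17410 genes were protein coding. The FPKM of a library summed to 322163 to 411378. FPKM times exon length gave whole numbers of a common step, within 0.05 read, for 92.8% to 93.3% of the nonzero values of a library, and in all 18 libraries within 0.1 read for 94.0% of genes. From this step the libraries held 14227763 to 17183681 reads assigned to genes, and 1 read in a gene of 1 kb gave 0.0582 to 0.0703 FPKM. PCR reads without molecular identifiers are not independent molecules, so depth covers counting error only.

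Genes with at least 1 FPKM in at least 3 of the 18 libraries were tested, 10320 in all. log2(FPKM + 1) was fitted with limma 3.58.1 in R 4.3.3 as 1 model of 6 group means with 12 residual degrees of freedom and a variance trend. Comparisons were KO against WT at each stage, MI and MII against GV within each genotype, and the difference between the genotypes in those changes. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. In KO against WT at 1 stage, rises and falls are differences between the genotypes, not changes over time. P-values are two-sided and were adjusted by Benjamini-Hochberg within each comparison, with a threshold of 0.05. No scaling between libraries was added to the deposited values. Tables and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

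Before the data were examined, 21 gene lists with 720 symbols were written from general knowledge, of which 683 symbols were found in the table. The lists cover RNP storage and P-body factors, deadenylation and decapping, cytoplasmic polyadenylation, cell cycle kinases, the APC/C and checkpoint, spindle and kinetochore, cohesin and condensin, zona and oocyte factors, maternal effect genes, dormant mRNAs, chromatin modifiers, ribosomal proteins, oxidative phosphorylation, the proteasome, mitochondrial mRNAs, p53 and apoptosis, stress, 2-cell embryo genes, and markers of cumulus and granulosa cells, of theca, stroma and endothelium, and of blood. In all, 24 symbols stand in more than 1 list. Lists with at least 5 tested members were compared with the other genes by limma's camera at a preset correlation of 0.01, and again with an estimated correlation. Only the zona and the maternal effect lists, in the difference between genotypes from GV to MII, passed with an estimated correlation. Sets of genes that changed at least 2-fold between stages in WT were tested by camera in KO against WT at the remaining stage.

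Named genes were Lsm14b, the 10 largest rises and falls of each KO against WT comparison, 5 each way of the stage changes in WT and of the differences between genotypes, and up to 4 members of each list with the smallest p. The first kinds needed an adjusted p under 0.05 and a mean of at least 5 FPKM, and the comparisons of 2 groups also no overlap between them. Predicted genes, clones and pseudogenes were left out by name, which removed 214, 200 and 281 of the 1310, 1042 and 1840 called genes with that mean at GV, MI and MII. From these, mostly genes whose call held without any 1 library are described, and some results are not reported here.

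On simulated data with 200 changed genes of 10320, a log2 change of 1 was recovered in 43%, 39% and 35% of genes at GV, MI and MII and a log2 change of 2 in 93%, 91% and 92%, and 4.9%, 5.7% and 5.9% of the calls were false. The changed genes were drawn from those with a mean log2(FPKM + 1) over 2, so the recovery rates do not cover lower genes. Further genes with a smaller shift were not counted as false when called. The simulated noise was independent between genes, with 1 SD per gene for all groups. In the data, deviations had an SD of 0.783 and 0.714 in KO GV replicates 2 and 3 and at most 0.49 outside that group. These rates may therefore not hold for the data, in particular at GV. Alternatives were pseudocounts of 0.1 and 5, no filter and a filter at 5 FPKM, median-of-ratios, quantile and TPM scaling, a fit of only the groups compared, a 2-fold minimum, the replicate number as a block, an estimated correlation, and leaving out each library. A fit of the recovered reads with voom and a fit with library quality weights were chosen after seeing the data. Voom on 9343 genes with whole reads called 1843, 1536 and 2851 genes in KO against WT at GV, MI and MII. The weights came from limma's gene-by-gene estimator; its default REML estimator had been run first and stopped before converging.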

Results

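RNA was measured in 18 libraries of 15 mouse oocytes each, in 6 groups of 3 replicates. Oocytes came from wild-type (WT) mice and from mice without Lsm14b (KO), at the germinal vesicle stage (GV), at metaphase I (MI) and 14 h after human chorionic gonadotropin (hCG). The labels denote the last time as MII for both genotypes and do not state whether each KO oocyte had reached metaphase II. Lsm14b encodes an RNA-binding protein of cytoplasmic ribonucleoprotein particles, and the series asks how its loss bears on the storage and clearance of maternal mRNA. The libraries held 14227763 to 17183681 reads assigned to genes, and 7352 to 9795 genes per library reached 1 FPKM.

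Stage and genotype set the libraries apart. The first principal component held 48.2% of the variance and ran from GV to MII, where WT libraries scored 75.6 to 83.1 and KO libraries 39.5 to 49.4. The second held 19.9% and placed every WT library below every KO library. KO GV replicate 2 stood apart from its group, with a first score of -62.9 against -40.8 to -49.8 for the other GV libraries, and Pearson correlations across genes within the KO GV group were 0.877 to 0.959, against 0.968 to 0.986 in WT GV. Genes are not independent replicates in these correlations.

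**Figure D1:**
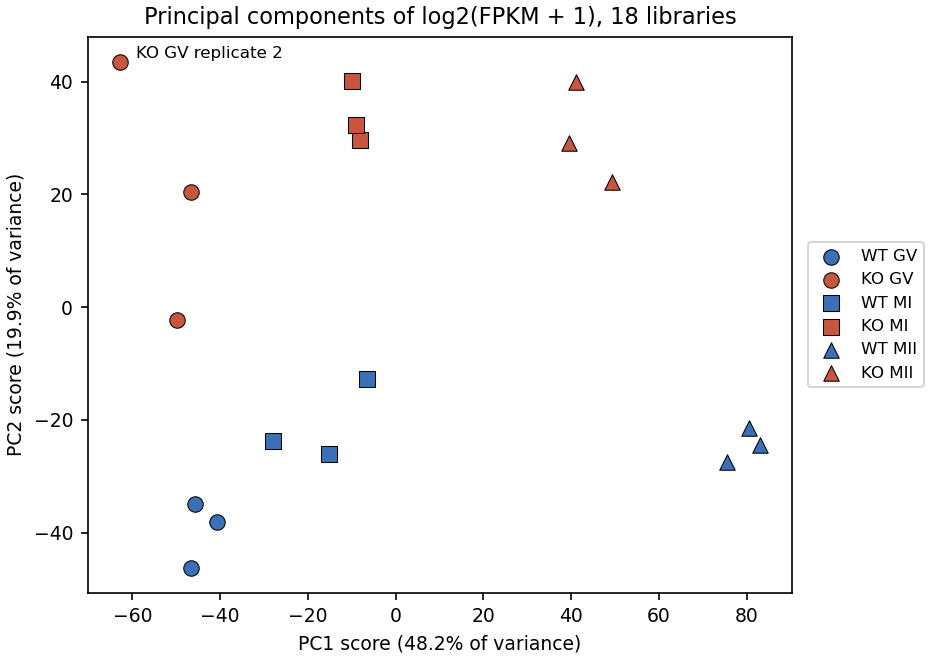
Scores of the 18 libraries on the first principal component (x axis, 48.2% of variance) and the second (y axis, 19.9%), both in units of log2(FPKM + 1). Colours mark the genotype and symbols the stage; KO MII libraries lie at 39.5 to 49.4 on the x axis, short of the WT MII libraries at 75.6 to 83.1.

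Lsm14b itself (ENSMUSG00000039108, chromosome 2, 180024987 to 180035465 on mm10 coordinates of the annotation used) was nearly absent from KO oocytes. WT oocytes held 2.30 ± 0.265 FPKM at GV, 7.08 ± 3.6 at MI and 9.34 ± 1.73 at MII (SD, n = 3). KO oocytes held 0.116 ± 0.117, 0.124 ± 0.0029 and 0.113 ± 0.095 FPKM at the same stages, from 0 to 10 reads per library. The fitted log2 changes were -1.56, -2.76 and -3.20, with adjusted p of 0.000313, 4.9e-07 and 3.91e-08. Its paralog Lsm14a stood at 13.3, 27.7 and 50.9 FPKM in WT and at 17.2, 32.4 and 40.2 in KO.

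At GV, before meiosis resumes, KO oocytes held less of several mRNAs that oocytes store for later translation. Dazl, which encodes a translational regulator of the germ line, stood at 334.5 ± 20.9 FPKM in WT and 76.4 ± 26.9 in KO (log2 change -2.17, SE 0.27, adjusted p = 4.23e-05). Btg4, an adaptor of the CCR4-NOT deadenylase that acts in maternal mRNA decay, stood at 3091 ± 1150 and 801.4 ± 49.3 FPKM (-1.88, adjusted p = 4.46e-05). Plat, which encodes tissue plasminogen activator, stood at 582.3 ± 80.8 and 91.1 ± 34.5 FPKM. Mos, the kinase upstream of MAPK in oocytes, fell from 245.9 ± 25.1 to 104.1 ± 10.1 FPKM and Fbxo43, an inhibitor of the anaphase-promoting complex, from 44.0 ± 1.78 to 15.6 ± 3.53 FPKM (SD, n = 3 throughout). Of 28 dormant mRNAs tested, 12 were lower and 0 higher, and the count was 12 when adjusted over the list alone. Their median log2 change was -0.60 against 0.174 for all genes (adjusted p = 2.24e-06 with a preset correlation, adjusted p = 0.115 with an estimated correlation).

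The largest falls at GV were in Pfdn4, a prefoldin subunit (505.1 ± 154 to 24.3 ± 0.929 FPKM, log2 -4.27), in Zc3h6, a zinc finger gene (75.1 ± 9.24 to 3.41 ± 0.662, log2 -4.11), and in Pabpn1l, an oocyte poly(A)-binding protein gene (135.7 ± 4.49 to 10.1 ± 4.45, log2 -3.69). Ccdc69, Exosc3, Tmem128, Pdcl3, Sar1b and Nedd4l fell with log2 changes of -2.50 to -3.46. Exons of other genes cover 28.7% of those of Pfdn4, which lies 9.5 Mb from Lsm14b. Bcl2l10, an abundant oocyte transcript of the Bcl2 family, fell from 11860 ± 767 to 3840 ± 869 FPKM. Among the larger rises were Tceal8 (4.87 ± 2.4 to 80.5 ± 40.7 FPKM, log2 3.73), Vrtn (7.88 ± 4.78 to 95.3 ± 77.2), Ftl1, the ferritin light chain (12.8 ± 2.34 to 86.3 ± 12.3), and Hsph1, a heat shock protein gene (15.7 ± 6.41 to 96.5 ± 44.4). The chaperone gene Hspa5 rose from 29.1 ± 7.45 to 142.7 ± 99.1 FPKM.

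In all, 2146 of 10320 genes passed an adjusted p of 0.05 at GV, 1373 higher and 773 lower in KO. The split followed the scaling: with median-of-ratios scaling 1087 were higher and 1445 lower, and with quantile normalization 1380 and 1347, while the median of all genes moved from 0.174 to -0.043 and 0.02. The count also followed single libraries: it was 1393, 1257 and 894 without WT GV replicate 1, 2 or 3, and 1214, 1015 and 4102 without KO GV replicate 1, 2 or 3. Higher and lower genes were 898 and 495, 691 and 566, and 431 and 463 without these WT replicates in turn. They were 628 and 586, 451 and 564, and 3024 and 1078 without the KO replicates. Of the 1015 without KO GV replicate 2, 903 were among the 2146. With only the groups compared, 92 were higher and 210 lower, and Hspa5, Vrtn and Bmp15 lost their calls. Of 78 named results at GV, 54 kept the call without any 1 library and 28 in every fit.

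Transcripts for ribosomal proteins were higher in KO at GV in 22 of 73 members (27 higher and 1 lower when adjusted over the list alone), with a median log2 change of 0.73 (adjusted p = 1.3e-05, adjusted p = 0.953 with an estimated correlation). Rps23 stood at 9.22 ± 3.57 FPKM in WT and 49.5 ± 27.8 in KO. The call was lost without KO GV replicate 2, in which these genes lay 1.43 log2 above the other KO GV libraries; 6 were then higher and 1 lower, with a median of 0.3 and an adjusted p of 0.0615. Nuclear genes of oxidative phosphorylation were higher in 15 of 71 members (16 adjusted over the list alone; median 0.44, adjusted p = 0.0218, adjusted p = 0.953 with an estimated correlation), and lay 1.00 log2 higher in KO GV replicate 2. That call was lost without WT GV replicate 2 (0.231), KO GV replicate 2 (0.235) or KO GV replicate 3 (0.081), and its adjusted p reached 0.0868 over the scalings tried, voom included. The median of this list ranged from 0.2 to 0.62 with 1 library left out and from 0.18 to 0.54 over these scalings. Among zona pellucida genes and oocyte growth and transcription factors, 5 of 27 were lower and 3 higher, counts that were the same when adjusted over the list alone (median -0.34, adjusted p = 0.0218, adjusted p = 0.549 with an estimated correlation). Bmp15, an oocyte growth factor, stood at 2206 ± 230 and 841 ± 368 FPKM and Oosp3 at 471 ± 13.8 and 100.6 ± 31.7, whereas the transcription factor gene Nobox rose from 270 ± 95 to 1041 ± 258. This call was lost without KO GV replicate 2 (0.211) and reached 0.251 over the scalings. The median of the zona list ranged from -0.38 to -0.12 with 1 library left out and from -0.61 to -0.29 over the scalings.

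**Figure D2:**
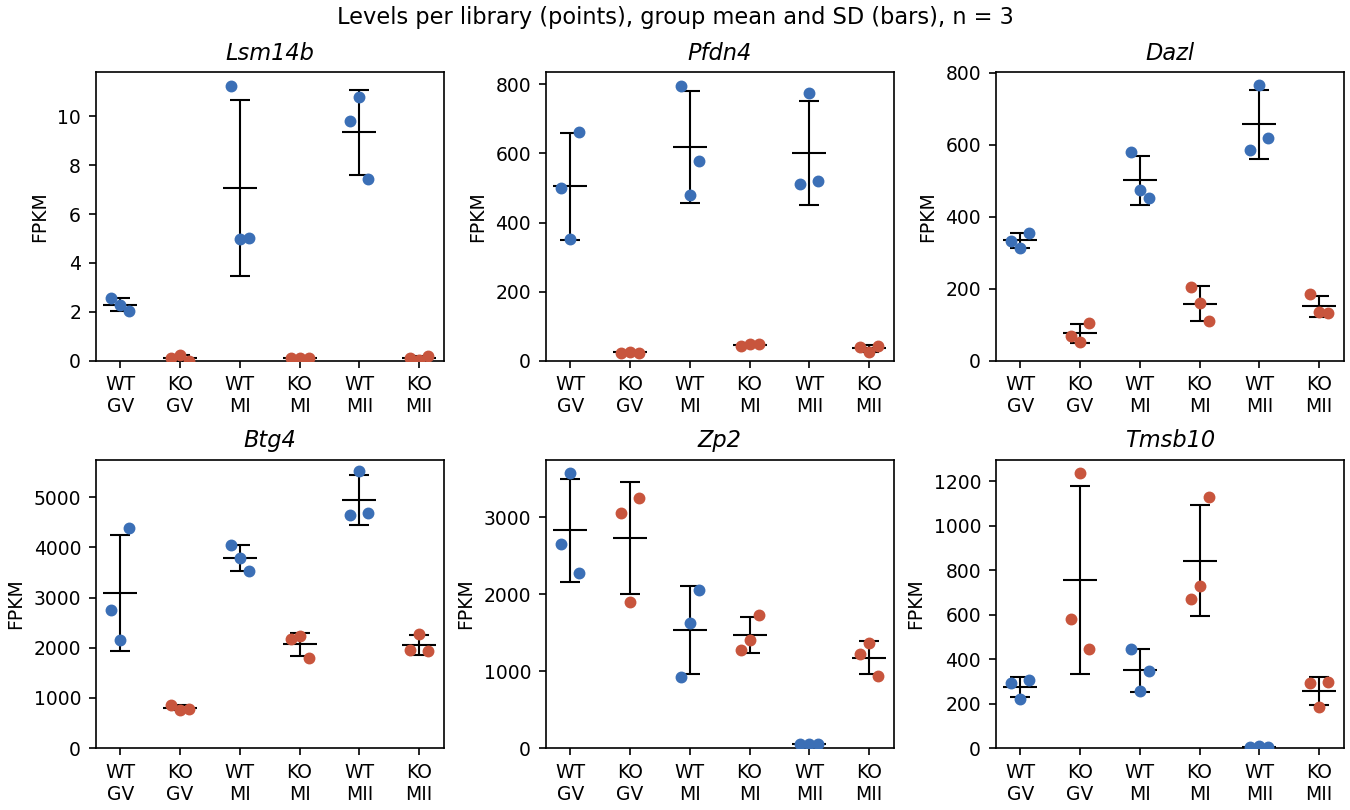
FPKM (y axes, linear, from 0) of Lsm14b, Pfdn4, Dazl, Btg4, Zp2 and Tmsb10 in each library (points) by genotype and stage (x axes), with the mean and SD of 3 replicates as bars. Dazl was lower in each KO library than in each WT library at the same stage, and Zp2 stood at 50.4 FPKM in WT MII against 1175 in KO MII.

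As deposited, most of the genes that differed at MI were lower in KO, by a margin that narrowed with median-of-ratios and quantile scaling. Exosc3, a subunit of the RNA exosome, stood at 70.4 ± 3.34 FPKM in WT and 3.23 ± 0.429 in KO (log2 -4.08, SE 0.31, adjusted p = 1.71e-07). Kdm7a, a histone demethylase gene, stood at 19.4 ± 7.48 and 1.11 ± 0.122 FPKM, and Smim20 at 30.9 ± 13.2 and 2.63 ± 0.115. Zc3h6, Pabpn1l and Pfdn4 were again among the largest falls, with log2 changes of -3.89, -3.77 and -3.65. C1galt1c1, Efna4 and the annotated T-cell receptor pseudogene Trav13-3 fell with log2 changes of -2.84, -2.73 and -2.77. Tceal8 rose from 0.821 ± 0.227 to 83.3 ± 76.5 FPKM (log2 5.14), the chemokine gene Ccl2 from 3.51 ± 2.18 to 20.5 ± 4.46, and Pabpc1, the somatic cytoplasmic poly(A)-binding protein gene, from 0.827 ± 0.595 to 7.38 ± 0.714. Sycp3 rose from 1.77 ± 0.802 to 15 ± 10.4, with 52.2% of its exon bases shared with other genes.

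Factors of mRNA deadenylation and decapping were lower at MI in 9 of 26 members and higher in 0 (13 lower and 2 higher when adjusted over the list alone). The decapping genes Dcp1a and Dcp2 stood at 96.0 ± 4.1 and 15.3 ± 6.22 FPKM in WT and at 35.2 ± 11.7 and 5.50 ± 0.416 in KO, and the deadenylase gene Cnot8 at 74.3 ± 16.9 and 28.4 ± 6.85. Of the dormant mRNAs, 8 were lower and 0 higher (10 lower when adjusted over the list alone), with Dazl at 501.9 ± 67.5 FPKM in WT and 159.2 ± 47.5 in KO. As lists neither passed the test: deadenylation had a median of -0.45 with an adjusted p of 0.151, and dormant mRNAs -0.39 with 0.163. No list passed at MI; the lowest adjusted p, 0.0574, was that of the subcortical maternal complex and maternal effect genes. Without WT MI replicate 3, KO MI replicate 2 or KO MII replicate 2, 1, 2 and 1 lists passed.

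In all, 1786 genes passed at MI, 375 higher and 1411 lower in KO. With median-of-ratios scaling 874 were higher and 1154 lower, and with quantile normalization 1068 and 1192, as the median of all genes moved from -0.132 to 0.015 and 0.035. The count was 1075 without WT MI replicate 2 and 1155 without KO MI replicate 3. The number higher was 179 without WT MI replicate 3 and 219 and 191 without KO MI replicate 1 or 2. The number lower was 769 without WT MI replicate 2 and 882 without KO MI replicate 3.

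At MII, some transcripts stood higher in KO and others lower. Zp2 and Zp3, which encode zona pellucida glycoproteins, stood at 50.4 ± 1.43 and 158.0 ± 36.9 FPKM in WT and at 1175 ± 217 and 1263 ± 300 in KO (log2 4.50 and 2.99, adjusted p = 1.62e-08 and 2.28e-06). Tmsb10, a thymosin that binds actin, stood at 7.29 ± 0.863 and 257.3 ± 63.7 FPKM (log2 4.93), and Cd9, an egg surface protein needed for sperm fusion, at 12.6 ± 4.85 and 239.7 ± 15.1. Cfl1, or cofilin, stood at 169.9 ± 40.9 and 1860 ± 146 FPKM. Chchd2, Ppp2r2b, Pinlyp, Rwdd1 and Tceal8 stood higher in KO than in WT by log2 3.54 to 4.57. The kinase gene Mapk3 stood at 24.5 ± 6.97 FPKM in WT and 249.3 ± 34.3 in KO, and Birc5, or survivin, at 118.7 ± 9.96 and 603.1 ± 154.

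Of 71 nuclear genes of oxidative phosphorylation, 35 were higher in KO at MII and 0 lower (41 when adjusted over the list alone; median 0.84, or 0.78 to 1.44 over the scalings and voom, adjusted p = 3.4e-09, adjusted p = 0.464 with an estimated correlation). Cox6a1 stood at 22.4 ± 3.32 FPKM in WT and 156.2 ± 58.5 in KO, and Ndufb3 at 6.90 ± 3.46 and 72.5 ± 23.0. Of 73 ribosomal protein genes 22 were higher and 2 lower (23 and 2 when adjusted over the list alone; median 0.36, or 0.3 to 1.42 over the scalings and voom, adjusted p = 0.000767, adjusted p = 0.812 with an estimated correlation), among them Rpl32 at 27.7 ± 8.12 and 162.9 ± 58.3 FPKM. Of 34 genes of the subcortical maternal complex and other maternal effect genes, 11 were higher and 1 lower (12 and 1 when adjusted over the list alone; median 0.54, adjusted p = 0.00391, adjusted p = 0.0533 with an estimated correlation). These included Tle6 (114.8 ± 31.7 and 608.9 ± 188 FPKM) and Nlrp5 (181.5 ± 14.8 and 726.6 ± 264). The zona and oocyte factor list had 10 higher and 3 lower members (10 and 4 when adjusted over the list alone) and did not pass, with an adjusted p of 0.0585.

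In the other direction, 12 of 26 deadenylation and decapping factors were lower in KO at MII and 1 higher (14 and 1 when adjusted over the list alone; median -0.73, adjusted p = 0.000996, adjusted p = 0.464 with an estimated correlation). The CCR4-NOT subunit genes Cnot3 and Cnot6 stood at 13.8 ± 3.26 and 4.14 ± 0.612 FPKM in WT and at 2.62 ± 0.432 and 0.989 ± 0.498 in KO, and Btg4 at 4945 ± 491 and 2053 ± 192. Dormant mRNAs were lower in 10 of 28 and higher in 2 (10 and 3 when adjusted over the list alone; median -0.57, adjusted p = 0.013, adjusted p = 0.464 with an estimated correlation), with Dazl at 657.1 ± 95.9 and 152.2 ± 28.9 FPKM. Cohesin, condensin and shugoshin genes were lower in 9 of 22 and higher in 1 (9 and 2 when adjusted over the list alone; median -0.53, adjusted p = 0.013, adjusted p = 0.567 with an estimated correlation), among them the cohesin genes Smc3 (46.5 ± 8.74 and 15.9 ± 4.94 FPKM) and Stag2 (6.82 ± 0.748 and 2.08 ± 0.612). Mitochondrially encoded mRNAs had a median of -0.77 with 2 of 12 lower (0 when adjusted over the list alone; adjusted p = 0.028, adjusted p = 0.722 with an estimated correlation). This last call was lost without WT MII replicate 2 (0.0735) or WT MII replicate 3 (0.0652), and reached 0.0531 over the scalings. The CPE-binding protein gene Cpeb4 stood at 16.8 ± 2.01 FPKM in WT and 2.59 ± 0.932 in KO. Zc3h6, Pfdn4, Kdm7a, Exosc3 and Pabpn1l were lower in KO with log2 changes of -3.42 to -4.45. In all, 2956 genes passed at MII, 1537 higher and 1419 lower, with a median of 0.007 for all genes.

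**Figure D3:**
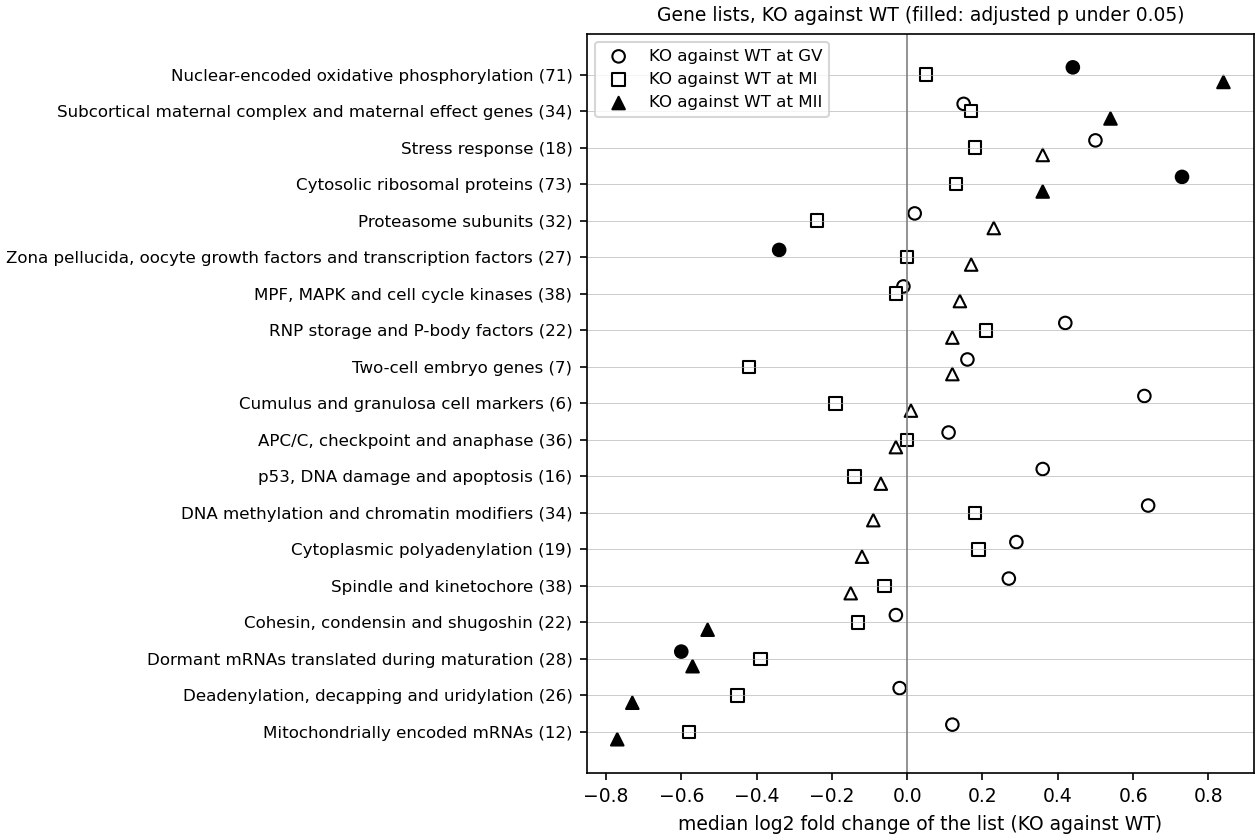
Median log2 fold change of KO against WT (x axis) for each gene list tested (y axis, members tested in brackets) at GV (circles), MI (squares) and MII (triangles). Filled symbols passed an adjusted p of 0.05 with a preset correlation: 4 lists at GV, 0 at MI and 7 at MII, none of which passed with an estimated correlation.

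The KO differences were shared between stages, which had no library in common. Across genes, the log2 changes at GV and MI correlated with Pearson r = 0.7, those at MI and MII with 0.606, and those at GV and MII with 0.422, where genes are not independent replicates. At GV and MI, 246 genes were higher in both and 530 lower in both, against 49.9 and 105.7 for independent calls, and 4 changed in opposite directions against 215.8. At MI and MII, 255 were higher in both and 751 lower in both, against 55.9 and 194, and 15 were opposite. At GV and MII, 410 were higher in both and 421 lower in both, against 204.5 and 106.3, and 25 were opposite. At all 3 stages 176 genes were higher and 350 lower, against 7.4 and 14.5 for independent calls; Dazl, Zc3h6, Pfdn4, Pabpn1l, Exosc3, Bcl2l10 and Fbxo43 were lower at each. One variance per gene served all comparisons, which by itself raises overlaps in the same and in opposite directions alike.

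**Figure D4:**
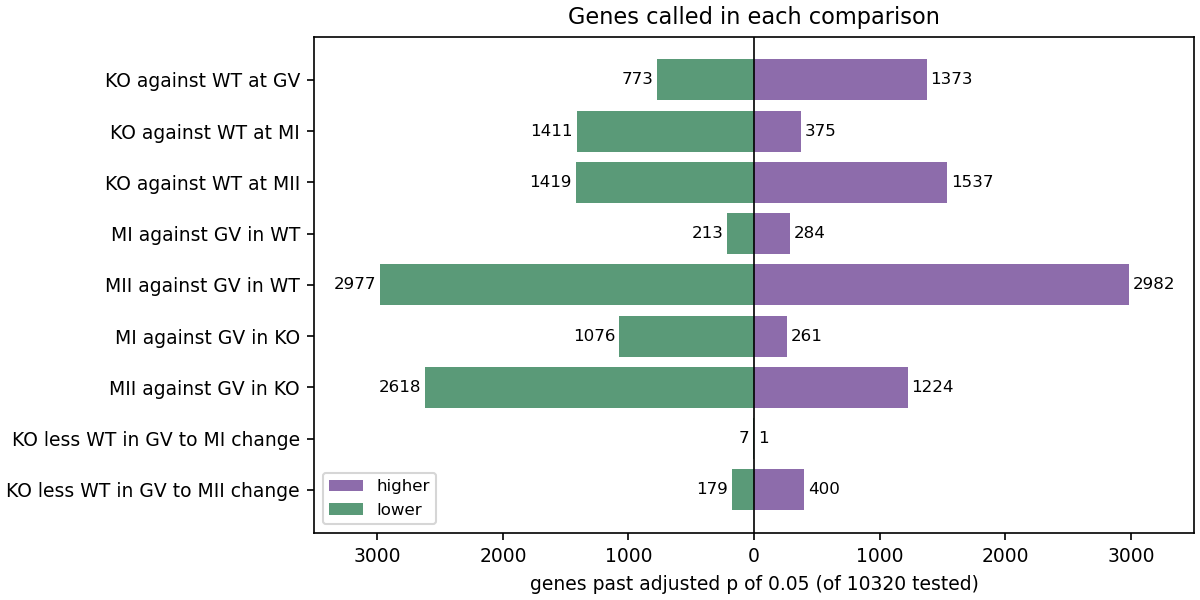
Number of genes past an adjusted p of 0.05 (x axis, from 0 to either side) in each of 9 comparisons (y axis), with genes higher in the first-named group to the right and lower ones to the left. KO against WT had 1373 higher and 773 lower at GV, 375 and 1411 at MI, and 1537 and 1419 at MII, splits that at GV and MI followed the scaling.

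In WT, 5959 of the 10320 genes tested changed from GV to MII, or 5810 of 27874 with no filter. Zp2 and Zp3 fell from 2834 ± 671 and 7664 ± 1260 FPKM to 50.4 ± 1.43 and 158.0 ± 36.9, and Cpsf4l from 309.3 ± 49.9 to 1.14 ± 0.356 (log2 -7.18, adjusted p = 2.93e-11). Upp1, Fam162a, Fcf1 and Bud31 fell with log2 changes of -6.68, -6.31, -6.16 and -6.0. Ribosomal protein genes fell in 65 of 73 members and rose in 0 (66 when adjusted over the list alone; median -2.42, or -4.16 to -2.19 over the scalings and voom, adjusted p = 4.54e-19, adjusted p = 0.342 with an estimated correlation), Rps13 from 81.2 ± 9.39 to 0.720 ± 0.237 FPKM. Nuclear genes of oxidative phosphorylation fell in 60 of 71 and rose in 1 (62 and 1 when adjusted over the list alone; median -2.44, or -3.52 to -2.23 over the scalings and voom, adjusted p = 4e-18, adjusted p = 0.279 with an estimated correlation), and proteasome subunits fell in 25 of 32 and rose in 2 (counts that were the same when adjusted over the list alone; median -1.63, adjusted p = 6.18e-08, adjusted p = 0.279 with an estimated correlation). The zona and oocyte factor list fell in 13 of 27 and rose in 2 (12 and 2 when adjusted over the list alone; median -0.53, adjusted p = 0.00538, adjusted p = 0.279 with an estimated correlation).

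Other transcripts rose from GV to MII in WT. All 12 mitochondrially encoded mRNAs rose (12 when adjusted over the list alone; median 1.81, adjusted p = 0.000159, adjusted p = 0.342 with an estimated correlation), mt-Nd2 from 161.3 ± 63.0 to 1879 ± 507 FPKM. Deadenylation and decapping factors rose in 12 of 26 and fell in 2 (counts that were the same when adjusted over the list alone; median 0.61, adjusted p = 0.00762, adjusted p = 0.421 with an estimated correlation), with the deadenylase gene Cnot6l at 18.8 ± 6.18 and then 92.1 ± 11.6 FPKM. Spindle and kinetochore genes rose in 20 of 38 and fell in 7 (21 and 7 when adjusted over the list alone; median 0.62, adjusted p = 0.0133, adjusted p = 0.342 with an estimated correlation), a call that reached 0.0505 over the scalings. Cohesin, condensin and shugoshin genes rose in 15 of 22 and fell in 3 (median 0.81, adjusted p = 0.0133, adjusted p = 0.421 with an estimated correlation), and DNA methylation and chromatin genes rose in 15 of 34 and fell in 2 (median 0.59, adjusted p = 0.0133, adjusted p = 0.568 with an estimated correlation). Both lists gave the same counts when adjusted over the list alone. Genes of p53, DNA damage and apoptosis rose in 8 of 16 and fell in 1, also when adjusted over the list alone (median 0.56, adjusted p = 0.0333, adjusted p = 0.421 with an estimated correlation), with Brca2 at 12.9 ± 1.47 and then 47.3 ± 4.59 FPKM. That call was lost without KO GV replicate 2 (0.0537) and over the scalings (0.0553). In all, 5959 genes passed, 2982 higher and 2977 lower at MII. The split was 2992 and 3321 with median-of-ratios scaling, 3987 and 2706 with quantile normalization, and 3747 and 2711 with TPM. FPKM are relative to the reads of each library, so these rises and falls need not be changes in the amount per oocyte.

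The step from GV to MI in WT gave 497 genes, 284 higher and 213 lower at MI. Bud31, a splicing factor gene, fell from 366.1 ± 50.3 to 81.6 ± 49.4 FPKM (log2 -2.30, SE 0.34, adjusted p = 0.00217), Cpsf4l from 309.3 ± 49.9 to 70.7 ± 42.7, and Fcf1 from 143.7 ± 43.6 to 34.0 ± 17.1. The mitochondrial mRNA mt-Nd2 rose from 161.3 ± 63.0 to 938.5 ± 356. Mitochondrially encoded mRNAs rose in 7 of 12 (10 when adjusted over the list alone; median 1.47, adjusted p = 3.59e-06, adjusted p = 0.368 with an estimated correlation). Proteasome subunits fell in 6 of 32 (7 when adjusted over the list alone; median -0.22, adjusted p = 2.26e-07, adjusted p = 0.368 with an estimated correlation). Ribosomal protein genes fell in 9 of 73 (16 fell and 1 rose when adjusted over the list alone; median -0.29, adjusted p = 7.22e-11, adjusted p = 0.689 with an estimated correlation). Nuclear genes of oxidative phosphorylation fell in 5 of 71 (9 when adjusted over the list alone; adjusted p = 1.42e-05, adjusted p = 0.689 with an estimated correlation), with a median of -0.04 that ranged from -0.32 to 0.05 over the scalings. The zona and oocyte factor list passed with 0 of 27 members past the threshold (5 lower when adjusted over the list alone; median -0.31, adjusted p = 1.42e-05, adjusted p = 0.091 with an estimated correlation). This comparison leaned on single libraries: the count was 87, 110 and 124 without WT GV replicate 1, 2 or 3, 40 and 1237 without WT MI replicate 1 or 3, 1438 and 1437 without KO GV replicate 2 or 3, and 322 without WT MII replicate 3. Higher and lower genes were 34 and 53, 23 and 87, and 36 and 88 without WT GV replicate 1, 2 or 3. They were 1 and 39, 72 and 297, and 1037 and 200 without WT MI replicate 1, 2 or 3. Without KO GV replicate 2 or 3 they were 1028 and 410, and 1073 and 364. Without KO MI replicate 1 or 2, WT MII replicate 1 or 3, or KO MII replicate 1, the number higher was 173, 188, 180, 158 and 185. With median-of-ratios scaling 151 genes were higher and 698 lower, and with quantile normalization 272 and 549, as the median of all genes moved from 0.241 to -0.037 and 0.037. Over the scalings and voom the list medians were -0.6 to -0.18 for the proteasome, -0.62 to -0.27 for ribosomal proteins and -0.66 to -0.23 for the zona list. With 1 library left out they were -0.36 to -0.17, -0.46 to -0.13 and -0.37 to -0.21.

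In KO oocytes, 1337 genes changed from GV to MI, 261 higher and 1076 lower at MI, and 3842 from GV to MII, 1224 higher and 2618 lower. The first count was 791 without KO MI replicate 1, with 99 higher and 692 lower, and without KO MI replicate 2 the number higher was 102. From GV to MII the number higher was 715 without KO MII replicate 1. With median-of-ratios scaling the splits were 547 and 1121 at MI and 2245 and 2484 at MII, and with quantile normalization 818 and 1076 at MI and 3078 and 2105 at MII. Of the 2174 genes that fell at least 2-fold from GV to MII in WT, 1430 also did in KO, against 398.4 for independent calls, and their median log2 change was -1.78 in WT and -1.38 in KO. Chosen by their fall in KO instead, 1891 genes had medians of -1.7 in WT and -1.67 in KO. Of the 1545 that rose at least 2-fold in WT, 177 did in KO, against 68.9, with medians of 1.31 and 0.47. The 460 chosen by their rise in KO had 0.81 in WT and 1.2 in KO. Each choice favours the genotype it was made in. From GV to MI, 131 of 162 fallen genes and 8 of 154 risen genes were shared, against 11.1 and 1.9. The 162 had medians of -1.37 in WT and -1.8 in KO, a larger fall in KO although chosen in WT. The 710 chosen by their fall in KO had -0.59 in WT and -1.39 in KO. The 154 had 1.23 in WT and 0.59 in KO, and the 124 chosen by their rise in KO had 0.6 and 1.19. All these medians cover every gene chosen, shared or not.

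The difference between the genotypes in these changes was tested directly. From GV to MII it passed for 579 genes, 400 with a higher and 179 with a lower change in KO. Zp2 fell from 2834 to 50.4 FPKM in WT and stood at 2735 and 1175 in KO (difference log2 4.57, SE 0.41, adjusted p = 9.58e-06). Zp3 stood at 7664 and 158.0 in WT and at 7023 and 1263 in KO, Cd9 at 146.5 and 12.6 in WT and at 155.2 and 239.7 in KO, and Ube2a, a ubiquitin-conjugating enzyme gene, at 51.6 and 5.81 in WT and at 52.9 and 49.1 in KO. Paip2, which encodes an inhibitor of poly(A)-binding protein, stood at 267.3 and 29.8 FPKM in WT and at 211.7 and 335.1 in KO. In the other direction, Kdm7a rose from 6.02 to 32.7 FPKM in WT and stood at 1.08 and 1.23 in KO. The zona and oocyte factor list had 5 higher and 0 lower members of 27, or 11 higher when adjusted over the list alone. Its median was 0.52 against -0.17 for all genes (adjusted p = 2.04e-05, adjusted p = 0.0475 with an estimated correlation). This median ranged from 0.41 to 0.89 with 1 library left out and from 0.27 to 0.85 over the scalings and voom. The subcortical maternal complex list had 6 higher and 0 lower of 34 (8 and 3 when adjusted over the list alone; adjusted p = 0.0139, adjusted p = 0.0475 with an estimated correlation), with a median of 0.09 that ranged from -0.01 to 0.4 over the scalings and an adjusted p of up to 0.233. Oxidative phosphorylation had 7 higher and 0 lower of 71, also when adjusted over the list alone (median 0.34, or 0.4 to 1 over the other scalings and voom, adjusted p = 0.000136, adjusted p = 0.778 with an estimated correlation). Cohesin, condensin and shugoshin genes had 1 lower of 22 (7 lower and 1 higher when adjusted over the list alone; median -0.65, adjusted p = 0.0198, adjusted p = 0.778 with an estimated correlation).

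The 579 depended on single libraries: the count was 267, 307 and 335 without WT GV replicate 1, 2 or 3, 362 and 2813 without KO GV replicate 1 or 3, 361, 277 and 231 without WT MII replicate 1, 2 or 3, and 215 and 374 without KO MII replicate 1 or 2. The split turned without KO GV replicate 3, where 794 had a higher and 2019 a lower change in KO. The number with a lower change was 59, 48 and 54 without the WT GV replicates in turn, and 75 and 83 without KO GV replicate 1 or 2. It was 56, 45 and 43 without the WT MII replicates, 33 and 47 without KO MII replicate 1 or 2, and 117 without KO MI replicate 1. The number with a higher change was 208 and 259 without WT GV replicate 1 or 2, 232 and 188 without WT MII replicate 2 or 3, and 182 without KO MII replicate 1. From GV to MI the difference passed for 8 genes, 1 higher and 7 lower, with 1383 at an unadjusted p under 0.05. Eif6, a ribosome biogenesis factor, went from 73.7 to 34.5 FPKM in WT and from 66.6 to 6.95 in KO (log2 -2.02, SE 0.29, adjusted p = 0.00561), a call lost with median-of-ratios scaling and with only the groups compared. The 1 higher gene, Gm48723, falls outside the rule for named genes and was chosen after its values were seen. Its call was lost, and 0 genes were higher, with a pseudocount of 0.1 or 5, a filter at 5 FPKM, quantile normalization, TPM, voom or only the groups compared, and without any 1 library other than KO GV replicate 3 or WT MI replicate 3. The count was 671 without KO GV replicate 3, 43 without WT MI replicate 3, 4 without WT MI replicate 2, and 5 without WT GV replicate 1 or 2, KO MI replicate 1, WT MII replicate 1 or 2, or KO MII replicate 1 or 2.

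Sets defined by the WT changes were then tested in KO against WT at the stage not used to define them. The 154 genes that rose at least 2-fold from GV to MI in WT were lower in KO at MII, with a median log2 change of -0.77 against 0.007 for all genes, 70 lower and 2 higher (adjusted p = 9.21e-15, adjusted p = 0.846 with an estimated correlation). This set leaned on 1 library: without WT MI replicate 1 only 1 gene was higher at MI in WT, too few to test. The 2174 genes that fell from GV to MII in WT had a median of -0.33 in KO at MI against -0.13 for all genes, 450 lower and 61 higher (adjusted p = 0.00476, adjusted p = 0.846 with an estimated correlation). The call of this set was lost without WT MI replicate 3, where the median was -0.376 against -0.225 for all genes (adjusted p = 0.0695), and with a filter at 5 FPKM or library quality weights. The median was -0.179 without WT MI replicate 2. The 67 genes that rose from MI to MII in WT had a median of -0.117 in KO at GV against 0.174 for all genes (adjusted p = 0.00963, adjusted p = 0.846 with an estimated correlation), a median that ranged from -0.364 without WT MII replicate 3 to 0.136 without WT MI replicate 1, where the call was lost. The call was also lost with a filter at 5 FPKM, median-of-ratios scaling, quantile normalization, TPM, where the median was 0.123 against 0.259 for all genes, and only the groups compared. The other sets did not pass: 162 genes that fell from GV to MI had a median of -0.045 at MII (0.389), 1545 that rose from GV to MII had -0.1 at MI (0.794), and 2027 that fell from MI to MII had 0.094 at GV (0.349).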

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

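The tests of linked strain variants, of scaling, of a uniform delay, and of GC content and length in KO GV replicate 2 were chosen after the results were seen. The others in this part were planned before their own results, but several address patterns already found in these data. The difference between the genotypes stood out in 3 places, each by a test of the difference itself: 8 genes in the change from GV to MI, 579 genes in the change from GV to MII, and 4 gene lists in the latter, of which the zona and oocyte factor list and the maternal effect list also passed with an estimated correlation (0.0475 each) and oxidative phosphorylation and cohesin did not (0.778 each).

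At MII, some transcripts that fell in WT from GV to MII, among them Zp2, Zp3 and Cd9, stood higher in KO. Scaling between libraries was not the whole cause, since 613 genes had a higher and 413 a lower change in KO with quantile normalization, and 826 and 334 with median-of-ratios scaling, against 400 and 179 as deposited. GC content and exon length explained 5.7% of the variance across genes of the difference between genotypes, and 692 genes had a higher and 578 a lower change in KO after each library was corrected for both. A uniform delay of maturation in KO, which would give like KO to WT ratios of the GV to MII change, cannot be told apart. The ratio was 0.91 for ribosomal protein genes (0.72 to 1.08 with 1 library left out), 0.96 for proteasome subunits (0.79 to 1), 0.78 for oxidative phosphorylation (0.64 to 0.82) and 0.18 for the zona and oocyte factor list (0.14 to 0.62). The first and last differed by 0.74, and the last rests on a small WT median of -0.53. Without KO GV replicate 2, however, the first 3 lists exceeded the last by 0.1, 0.17 and 0.02, and without KO MII replicate 3 by 0.34, 0.37 and 0.18. The ratios therefore do not decide. A delay before MI would leave genes that fall early in WT higher in KO at MI. The 2174 genes that fell from GV to MII in WT had a median of -0.33 there, against -0.13 for all genes. This does not decide, since 162 genes fell 2-fold from GV to MI in WT and 2027 from MI to MII. The call was lost without WT MI replicate 3 (median -0.376 against -0.225) and with an estimated correlation (camera, adjusted p = 0.846). Levels at MI also carry differences already present at GV. From GV to MI the 162 genes had medians of -1.37 in WT and -1.8 in KO. On the first component, KO MII libraries lay at 39.5 to 49.4 against 75.6 to 83.1 in WT MII, which a delay could also give. At MI, KO libraries lay at -9.9 to -8.2 and WT libraries at -27.9 to -6.5, so no lag showed there on this component. The genotype remains a biological explanation, as does a KO oocyte at 14 h after hCG that had not reached metaphase II, which the labels do not settle.

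KO GV replicate 2 lay apart from the other KO GV libraries. The SD of its log2 deviations was 0.783 as deposited and 0.698 after correction for GC content and length, against at most 0.482 in libraries outside the group and 0.619 in KO GV replicate 3, so these trends were not its whole cause. RNA of ovarian somatic or blood cells would have raised their markers, but the median deviation of 43 detected markers was 0.009, and 19 were higher in this library than in both others. These were 14 of 26 cumulus and granulosa, 4 of 9 theca, stroma and endothelium, and 1 of 8 blood markers. Most of the 43 lay below 1 FPKM in this library, where log2(FPKM + 1) moves little, so the median can miss a small contribution. The most abundant of these markers in this library were Bex4 at 23.6 FPKM, Myh11 at 17.4 and Ms4a1 at 8.74, and Ms4a1 reached 40.5 FPKM in a WT MII library. Oocytes of a later stage in the library cannot be told apart from other sources: genes that rose from GV to MI in WT lay 0.589 log2 higher in it against 0.28 for all genes, while genes that fell lay at -0.06 and its score on the first component, -62.9, was farthest from MI.

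The 350 genes lower in KO at all 3 stages could in part reflect strain variants linked to Lsm14b on chromosome 2. Of the 349 other than Lsm14b, 1.43% lay within 20 Mb of it, against 1.12% of 10319 tested genes (Fisher's exact test, two-sided, p = 0.599), so linkage does not account for the set as a whole. Pfdn4, Tfap2c, Prelid3b, Zfp931 and Gm14272 are the 5 that lie in this window, and for them linked variants remain open; all but Pfdn4 fall outside the rule for named genes and were chosen after their values were seen. Reads shared with overlapping genes do not account for it either: 0 of 350 genes shared over 50% of their exon bases, against 65 of 9963 other genes, a ratio of 0. The loss of Lsm14b is the biological explanation that the design offers, found and tested on the same data.

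For 3 libraries against 3, 10 splits exist, so a share under 0.05 cannot be reached. The real split of KO and WT at GV gave 2146 genes and the highest other 1, with 1 of 10 as large. At MI these were 1786 and 1 with 1 of 10, and at MII 2956 and 0 with 1 of 10. In WT they were 497 and 1 with 1 of 10 for MI against GV, and 5959 and 0 with 1 of 10 for MII against GV. In KO they were 1337 and 4 with 1 of 10 for MI against GV, and 3842 and 0 with 1 of 10 for MII against GV. Gene lists past the threshold, at a preset correlation, came out in other splits too: at GV 7 of 10 splits gave as many as the real 4, with 7 as the highest other; at MI 10 of 10 gave as many as the real 0, with 4 as the highest; and at MII 1 of 10, with 7 real and 5 as the highest other. For MI against GV in WT 4 of 10 splits gave as many as 5, with 8 as the highest other, and for MII against GV 2 of 10 gave as many as 10, with 10 as the highest.

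For the sets from WT, values are sizes of the median log2 change of the set. The median of all genes was not subtracted, so a shift of all genes enters these values. Genes that rose from GV to MI gave 0.771 at MII and at most 0.524 in other splits, with 1 of 10 as large; genes that fell gave 0.045 against 0.183, with 6 of 10. Genes that fell from GV to MII gave 0.331 at MI against 0.297, with 1 of 10, and those that rose 0.1 against 0.292, with 7 of 10. Genes that fell from MI to MII gave 0.094 at GV against 0.203, with 6 of 10, and those that rose 0.117 against 0.37, with 4 of 10.

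For the differences between genotypes, 100 splits were drawn. From GV to MI, 11 of 100 gave as many as 8 genes. From GV to MII, 12 of 100 gave as many as 579, and 63 of 100 gave as many as 4 lists, with 8 as the highest. Genotypes were shuffled within each stage, so a split that mixed only 1 stage kept the genotype effect of the other. These counts therefore cannot decide on chance, which was not excluded. The highest other splits gave 3460 and 3809 genes. In these the genotypes were exchanged at 1 stage, so that they added the genotype effects of both stages, a structure of the samples. Leaving them out, the highest were 408 and 2429, and these splits may still hold the genotype effect of 1 stage.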

How the results depend on the processing

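No named result with an adjusted p under 0.05 changed direction. In all, 407 such results for 257 genes were rerun. Calls were lost 85 times with only the groups compared, 73 with no filter, 35 with median-of-ratios scaling and 593 in all over the 18 fits without 1 library. Named list members that had not passed the threshold were left out of these counts, also where their direction changed. Where not stated, the cause was not tested. Fits with voom and with library quality weights were chosen after seeing the data. The weights gave KO GV replicate 1 a weight of 4.05 against 0.21 and 0.244 for replicates 2 and 3, so that 1 library nearly stands for its group and the spread of the group counts for little. The default estimator gave it 49.2 without converging; its counts were 6964, 2633 and 5348 for KO against WT at GV, MI and MII. At the depth of these libraries 1 read in 1 kb is worth 0.0582 to 0.0703 FPKM, so that low genes rest on few reads. A filter at 5 FPKM tests fewer genes and a 2-fold minimum removes small changes.

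KO against WT at GV gave 1427 genes with a filter at 5 FPKM, 302 with only the groups compared (92 higher and 210 lower), 5271 with weights, 1199 at 2-fold and 894 to 4102 with 1 library left out. At MI these were 1157 with the filter, 926 at 2-fold and 1075 to 2280. At MII they were 5079 with weights, 1734 at 2-fold and 2227 to 3489. With the replicate block, the counts were 2040 at GV, 1751 at MI and 2924 at MII, and 6 (0 higher) and 443 for the differences between genotypes from GV to MI and to MII. The numbers did not pair the samples as a whole: of 45 pairs of libraries with the same number in different groups, 14 had deviations from their group means that correlated above 0.1, over a range of -0.52 to 0.42, and 5 of 18 libraries matched best with their own number. Between KO MI and KO MII, which were not compared, all 3 pairs lay above it, at 0.24, 0.26 and 0.42.

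MI against GV in WT gave 302 genes at a pseudocount of 0.1, 195 with no filter, 849 with median-of-ratios scaling, 821 with quantile normalization, 2537 with weights, 316 at 2-fold and 40 to 1438 with 1 library left out. MII against GV in WT gave 3925 with a filter at 5 FPKM, 3719 at 2-fold and 4977 to 6387. In KO, MI against GV gave 414 with only the groups compared, 3735 with weights, 834 at 2-fold and 791 to 1881. MII against GV gave 2546 with the filter, 2432 with only the groups compared, 2351 at 2-fold and 3048 to 4184.

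The difference from GV to MI gave 5 genes at a pseudocount of 0.1, 4 at 5, 14 with no filter, 4 with a filter at 5 FPKM, 5 each with median-of-ratios and quantile scaling, 1 with only the groups compared, 4 with voom, 1107 with weights and 4 to 671 with 1 library left out. From GV to MII it gave 268 with no filter, 1160 with median-of-ratios, 1026 with quantile, 4146 with weights and 215 to 2813. The split of the latter turned to 1663 higher and 2483 lower with weights, and to 794 and 2019 without KO GV replicate 3.

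Lists past the threshold in KO against WT at GV were 2 with median-of-ratios, 0 with an estimated correlation, 1 with weights and 1 to 5 with 1 library left out. At MI they were 3 with no filter, 1 with TPM, 1 with only the groups compared, 3 with voom, 1 with weights and 0 to 2. At MII they were 0 with an estimated correlation and 6 to 8. For MI against GV in WT they were 12 with no filter, 8 with quantile, 0 with an estimated correlation and 5 to 8, and for MII against GV 0 with an estimated correlation and 9 to 10. For the difference from GV to MII they were 10 with no filter, 2 with a filter at 5 FPKM, 2 with an estimated correlation, 9 with weights and 4 to 8.

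Of the WT sets, genes that fell from GV to MI had a median at MII of 0.001 at a pseudocount of 0.1, 0.035 with median-of-ratios, 0 with only the groups compared, 0.109 with weights and -0.1 to 0 with 1 library left out. Those that rose had -0.771 with an estimated correlation, where the call was lost, and -1.044 to -0.558; without WT MI replicate 1 too few genes rose to test. Genes that fell from GV to MII had -0.268 at MI with a filter at 5 FPKM, -0.331 with an estimated correlation, -0.232 with weights, each without the call, and -0.418 to -0.179. Those that rose had 0.1 with median-of-ratios, 0.059 with quantile and -0.258 to 0.054. Genes that fell from MI to MII had -0.149 at GV with median-of-ratios, -0.013 with quantile, 0.026 with weights, where the set was called, and 0.011 to 0.177. Those that rose lost the call at -0.134 with a filter at 5 FPKM, -0.173 with median-of-ratios, -0.054 with quantile, -0.048 with only the groups compared and -0.117 with an estimated correlation, turned to 0.123 with TPM, and ranged from -0.364 to 0.136.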

Other observations

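The test of an element in 3′ UTRs was chosen after the results were seen. In lists not described so far, single members passed while the lists did not in KO against WT. Of 18 stress response genes, 6 were higher in KO at GV and 0 lower (8 when adjusted over the list alone; median 0.50, adjusted p = 0.089), and 4 were higher and 1 lower at MII (counts that were the same when adjusted over the list alone; median 0.36, adjusted p = 0.184). At MII Sqstm1, an autophagy receptor, stood at 2.42 ± 0.72 FPKM in WT and 12.4 ± 2.25 in KO, and Atf4, a transcription factor of the integrated stress response, at 68.0 ± 7.07 and 243.3 ± 86.8. Ern1, a sensor of unfolded proteins, stood at 139.1 ± 8.28 and 45.4 ± 11.9. Among RNP storage factors, Patl2 stood at 3.37 ± 1.02 FPKM in WT MII and 31.8 ± 7.96 in KO MII, and Zar1l at 240.1 ± 33.9 FPKM in WT GV and 8.94 ± 2.48 in WT MII. Among spindle genes, Cenpa, the centromeric histone, stood at 6.11 ± 0.284 FPKM in WT MII and 1.5 ± 0.607 in KO MII, and Cenpe, a kinetochore motor, at 141.8 ± 7.69 and 71.7 ± 3.96. Among 2-cell embryo genes, Tcstv3 stood at 26.1 ± 8.67 FPKM in WT MI and 8.41 ± 1.68 in KO MI.

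These and the remaining lists did not pass in KO against WT at MII. RNP storage factors had 4 higher and 2 lower of 22 (adjusted p = 0.839), cytoplasmic polyadenylation 4 and 3 of 19 (0.892), cell cycle kinases 8 and 4 of 38 (0.547) and the APC/C and checkpoint 8 and 5 of 36 (0.888). Spindle and kinetochore genes had 5 and 8 of 38 (0.294), chromatin modifiers 4 and 3 of 34 (0.892), proteasome subunits 8 and 3 of 32 (0.108), p53 and apoptosis 2 and 3 of 16 (0.802), and 2-cell embryo genes 1 and 1 of 7 (0.892). When adjusted over the list alone, the counts were 9 and 5 for cell cycle kinases, 9 and 5 for proteasome subunits and 3 and 3 for p53 and apoptosis, and the same as above for the other 6 lists. Of the markers of cumulus and granulosa cells, 6 of 31 in the table passed the filter, with 2 higher in KO at GV (2 when adjusted over the list alone; median 0.63, adjusted p = 0.208), Fshr at 0.260 ± 0.0793 FPKM in WT and 1.48 ± 0.418 in KO. Only 4 theca, stroma and endothelium markers and 2 blood markers passed the filter, too few to test as lists; Cd68 stood at 0.642 ± 0.12 FPKM in WT MII and 2.18 ± 0.824 in KO MII (adjusted p = 0.0085). Lyz2 reached 27.5 FPKM in WT MI replicate 2 and at most 4.69 in the other libraries.

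A hypothesis was that genes lower in KO at all 3 stages may carry cytoplasmic polyadenylation elements (TTTTAT or TTTTAAT) near the 3′ end more often than others. Of 268 protein-coding genes of this set with an annotated 3′ UTR, 33.2% had the element in the last 100 bases, against 16% to 25.4% in 10000 random sets matched on UTR length and expression. AT-rich ends could give this without the element: in sets matched also on the GC content of these bases the range was 20.5% to 30.2%, and 99.85% of sets lay below the observed share, while a control motif of like composition stood at 32.1% within its range of 22.8% to 32.8%. Genes lower at GV had 28.0%, those lower at MII 30.7% and those that rose in WT from GV to MII 31.0%, above ranges matched also on GC content of 20.7% to 27.3%, 21% to 25.5% and 21.2% to 25.5%. The control motif also lay above its ranges, at 29.4% (22.1% to 28.7%), 29.4% (23.9% to 28.7%) and 29.5% (24.1% to 28.4%). Genes that fell in WT lay below with 9.0% (15.4% to 18.7%), as did their control motif with 12.2% (14.6% to 17.8%), so these contrasts were not specific to the element. Genes lower at MI had 19.9%, within 16.5% to 20.9%. Genes higher in KO at GV and MI had the element less often, at 16.6% (17.8% to 22%) and 17.5% (19.4% to 27.8%), with the control motif within its ranges at 19.9% (18.9% to 23.1%) and 21.6% (20.3% to 29.4%). At MII both lay below, at 15.8% (18.8% to 22.8%) and 17.5% (19.4% to 23.5%). The share at MI lay within 16.6% to 25.3% without the match on GC content, and genes higher at all 3 stages had 20.4%, within 15.9% to 28%, so these do not point 1 way. With oligo(dT) priming, an element that sets poly(A) tail length may change the measured level without a change in the amount of mRNA, and these libraries cannot tell these apart.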
